A study of Gallus gallus with 9 samples.

How the data were processed

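RNA of facial prominences from stage 18 chicken embryos, incubated at 38 degrees C, was measured on Affymetrix chicken arrays. Per the labels' protocols, biotinylated cRNA was made with the 2-cycle Affymetrix procedure from 500 ng of total RNA of pools of 26 to 32 pieces, and 3 pools each of the mandibular prominence, the maxillary prominence and the frontonasal mass were taken as biological replicates. The p values measure the spread between these pools. Samples were grouped by the prominence named in their titles. Scan dates and batches are not given in the sources used here.

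The deposited values are linear probe set intensities of 38535 probe sets on each of 9 arrays. The software that summarised probes to probe sets is not given in the sources used here. The mean of each deposited column without the highest and lowest 2% of values was 150.03, so the authors' arrays had already been scaled to a common level. No columns of other samples were present. From the deposited intensity, 96 control probe sets were left out, the arrays were scaled to the same median (factors 0.961 to 1.04), and log2(signal + 16) was used for all tests, so that fold changes of dim genes are understated. The design had been fixed before the unit was known, with this transformation for the case of linear values. Background on each array was the 95th percentile of 598 probe sets for viral and reporter sequences, which gave 31.6 to 37.1. A gene not above background on any of the 3 arrays of its dimmer group has only a bound there. The fold is then given as at least the mean log2 signal of the brighter group against that of the dimmer one with each array's background as the lowest value, and no fold is given where both groups lie below background.

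Probe sets were named from the platform annotation supplied with the data, in which 27168 tested probe sets had 1 gene, 177 several and 11094 none, and no gene was named from a probe set with several. Symbols were brought up to date through the gene identifiers of a reference gene table (assembly GRCg7b), which held 26853 of the 27168. That table was used for names and for which genes are neighbours. A gene was represented by its probe set with the highest mean over all arrays, which gave 13009 genes.

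Differences were tested with limma 3.58.1 in R 4.3.3. One model of group means was fitted to all 9 arrays (6 residual degrees of freedom), with moderated statistics, the 3 pairwise contrasts and Benjamini-Hochberg adjustment over all probe sets of a contrast. A call is an adjusted p under 0.05, and log2 differences are given with their standard errors. A moderated F test covered all 3 prominences. Probe sets were counted as setting a prominence apart when called in the same direction against both others. Overlaps between contrasts that share arrays were set against simulated data without any effect and against independent lists. The distance between prominences was the root mean square difference of group means after removal of the replicate variance, with a jackknife SE over arrays and a two-sided exact permutation test of differences between distances.

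Before the data were examined, 26 gene lists were fixed: frontonasal transcription factors, ventral arch and endothelin programme, maxillary and proximal arch programme, HOX genes, the WNT, BMP, FGF, hedgehog, retinoid and notch pathways, guidance cues, skeletal progenitors, neural crest mesenchyme, surface and oral epithelium, pharyngeal endoderm and thyroid, branchiomeric muscle and arch mesoderm, sensory and cranial neurons, nasal placode with lens and eye, forebrain, erythroid cells, endothelium, leukocytes, cell cycle, hypoxia, immediate early and heat shock genes, and W chromosome genes. The 25 lists with at least 5 measured genes were tested with camera (preset correlation 0.01) on 1 probe set per gene, with Benjamini-Hochberg adjustment over 75 tests, with an estimated correlation and with fry as alternatives. Fry tests whether a list moves on balance in one direction, without reference to other genes. Of 28 list calls none held with an estimated correlation, where the smallest adjusted p was 0.0948. Fry called 22 of the 75 tests, not all of them among the 28. It also called the maxillary and proximal arch list in both comparisons with the frontonasal mass (fry adjusted p = 0.00081 each). Between mandibular and frontonasal pools it also called the BMP list (0.0492) and the nasal placode list (0.0452). Some camera calls were not made by fry. These were endoderm between mandibular and frontonasal pools (fry adjusted p = 0.066), and crest (0.0932), erythroid (0.0926) and endothelium (0.0927) between maxillary and frontonasal pools. Between mandibular and maxillary pools they were frontonasal transcription factors (0.162), retinoid (0.312), crest (0.25), epithelium (0.0818), endoderm (0.134) and endothelium (0.249).

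Genes were named by a rule fixed at the same time: a panel of 36 craniofacial genes, the 8 largest differences in each direction per comparison among called genes whose arrays did not overlap (placeholder symbols left out), and up to 4 called members with the smallest p per list and comparison. Genes of frontonasal pool 2 (FGB, TTR, APOA1, GATA5, HOXA3, COL3A1, ISL1, NKX2-5) and other list members given only by name fall outside it and were chosen after their values were seen.

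The fit was tested on simulated data with the real means and spreads of 38439 probe sets and changes planted in 74, 71 and 55 of them. Recovery at 1.5-fold, 2-fold and 4-fold was 21.6%, 87.3% and 100% for mandibular against frontonasal pools, 23.0%, 76.1% and 98.2% for maxillary against frontonasal pools and 25.7%, 76.1% and 100% for mandibular against maxillary pools. False calls made up 7.64%, 3.10% and 8.57% of all calls. In a simulated list test, 2 of 2 planted shifts were called and 0 of 73 other tests. The simulated genes varied independently, so this cannot show how correlation between genes affects list calls. Other splits of the real arrays, described further on, called up to 17 list tests.

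Alternatives fixed beforehand were the replicate number as a block, quantile normalization, median centring, unscaled values, a pseudocount of 1, leaving out the dimmest 40% of probe sets, 1 probe set per gene, limma-trend, array weights, fits to only 6 arrays, a minimum log2 difference of 1, a test against a minimum fold of 1.5, the mean of all probe sets per gene for lists, and leaving out each array in turn. The split into higher and lower calls without frontonasal pool 2, and 7 marker lists of visceral and other tissues, were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Coordinates are not given, since the assembly behind the annotation is not named in the sources used here.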

Results

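Gene expression was measured in the facial buds of untreated chicken embryos at Hamburger Hamilton stage 18, an early stage at which the buds have formed but skeleton and muscle have not yet differentiated. The mandibular prominence gives rise to the lower jaw, the maxillary prominence to the sides of the upper jaw, and the frontonasal mass, dissected here from the region between the nasal pits, to the middle of the upper beak. Each bud contained neural crest derived mesenchyme and its covering epithelium. Pools of 26 to 32 pieces were frozen, and 3 pools per prominence, called biological replicates in the labels, were each hybridised to 1 Affymetrix chicken array, which gave 9 arrays. The deposited signals had medians of 34.3 to 37.3 intensity units, and 49.2% to 53.3% of the 38439 tested probe sets lay above the background of their array. The ratio of 3' to 5' signal, a sign of RNA quality and labelling, was 1.88 to 2.46 for actin. For GAPDH it was 1.51, 1.27 and 1.38 in the frontonasal pools against 1.19 to 1.29 on the 6 other arrays, and for EF1a 1.61, 1.42 and 1.35 against 1.21 to 1.44. Median correlations of an array with the others of its group were 0.979 to 0.987, lowest in the frontonasal group. The number of arrays limits the precision of all values.

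The frontonasal mass stood furthest from the other prominences. Across all tested probe sets, the root mean square log2 difference, corrected for replicate spread, was 0.232 ± 0.029 (jackknife SE) between mandibular and frontonasal pools, 0.221 ± 0.024 between maxillary and frontonasal pools, and 0.108 ± 0.039 between mandibular and maxillary pools. Each of the 3 differences between these distances had a two-sided exact permutation p of 0.1, the smallest that the 20 assignments of 6 arrays allow, so the design could not take any of them below 0.05. In limma's moderated F test, 1014 probe sets (2.64%) differed among the prominences at an adjusted p under 0.05. This count was 627 without mandibular pool 2, 656 without mandibular pool 3, 673 without maxillary pool 2 and 648 without frontonasal pool 1.

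The first comparison asked how the lower jaw bud differs from the frontonasal mass. LHX8, a LIM homeobox regulator of jaw and palate mesenchyme, had a mandibular signal of 1002 ± 39.8 (SD, n = 3) against 18.6 ± 9.68 in the frontonasal pools, at least 29.6-fold higher, and its log2 difference was 4.92 ± 0.19 (SE, limma adjusted p = 2.12e-05). MAB21L1, which is needed for normal eye and craniofacial development, was at least 16.7-fold higher in the mandibular pools, and DLX1, a homeobox gene of the proximal pharyngeal arch, at least 3.9-fold. In the other direction SP8, a zinc finger regulator of outgrowth and of the anterior neural border, was at least 18.9-fold higher in the frontonasal mass, ZIC1 at least 8.93-fold and SIX3, a forebrain and lens determinant, at least 5.65-fold. ALX1, a homeobox gene of the frontonasal mesenchyme, was lower in the mandibular pools by a log2 difference of -2.31 ± 0.14 (adjusted p = 0.000187, n = 3 per group).

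In total 974 probe sets differed between mandibular and frontonasal pools (limma, adjusted p under 0.05), 454 higher and 520 lower in the mandibular prominence, and 350 of them differed by at least 1 on the log2 scale. Among called genes without overlap between the arrays of the groups, the 8 with the largest positive differences were LHX8, MAB21L1, HAND2, WNT2B, BHLHE22, DLX1, EPHA3 and HDAC9, with fitted log2 differences from 4.92 down to 2.48, of which those of genes below background in the frontonasal mass depend on the pseudocount. The 8 largest negative differences belonged to SP8, ZIC1, NHLH2, SIX3, SOX3, OPTC, CPNE4 and SOX8 and ran from -4.05 to -2.60. SOX3, a SOXB1 gene of neural progenitors and placodes, and NHLH2, a neuronal helix-loop-helix gene, were at least 7.65-fold and 8.94-fold higher in the frontonasal mass. PAX6, required for eye and nasal placode formation, differed by -1.84 ± 0.18 and TBX22, a T-box gene of palate development, by -2.41 ± 0.28 (adjusted p = 0.00154 and 0.00327). A fit to only the 6 mandibular and frontonasal arrays called 613 probe sets. Without mandibular pools 1, 2 or 3 or frontonasal pool 1 the count of probe sets was 545, 526, 559 or 634. Without frontonasal pool 2, which carried transcripts of visceral organs described further on, it was 1089, of which 592 were higher and 497 lower. The GAPDH ratio of 3' to 5' signal was 1.28, 1.24 and 1.23 in mandibular and 1.51, 1.27 and 1.38 in frontonasal pools.

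The lists of ventral arch genes and of frontonasal transcription factors, which share DLX5, were called in opposite directions, each through part of its members. Of 21 measured genes of the ventral arch and endothelin programme, 7 were higher in the mandibular pools, 1 was lower and 13 did not pass, and adjusted over the list alone 11 were higher and 1 lower. This list was called higher (camera, adjusted p = 5.91e-06), but not when the correlation between genes was estimated (adjusted p = 0.0948 with an estimated correlation). MSX2, a BMP target in distal arch mesenchyme, rose by 2.24 ± 0.24, MSX1 by 1.04 ± 0.12 and PITX1, a regulator of lower jaw development, by 1.14 ± 0.14. GSC, whose frontonasal signal lay below background, was at least 1.98-fold higher. The endothelin receptor gene EDNRA was the member that was lower, at -1.06 ± 0.14. HAND2, a distal arch regulator that acts downstream of endothelin signalling, rose by 2.78 ± 0.43 (adjusted p = 0.0123), DLX6 by 1.48 ± 0.23 (0.0123) and DLX5 by 0.74 ± 0.15 (0.0388). These 3 calls were lost in 3, 2 and 7 of the 9 fits that left out 1 array, with the highest adjusted p values of 0.0553, 0.0563 and 0.14 without mandibular pool 1. Without frontonasal pool 2 the limma adjusted p was 0.000333 for HAND2 (log2 difference 3.36), 0.0315 for DLX6 and 0.0801 for DLX5.

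Of 18 measured frontonasal transcription factors, 9 were lower in the mandibular pools, 1 was higher (DLX5) and 8 did not pass. Adjusted over the list alone, 9 were lower and 3 higher, and the list was called lower (adjusted p = 5.91e-06, and adjusted p = 0.209 with an estimated correlation). Beyond ALX1 and SP8 its members included EYA2, a transcriptional coactivator of placode and muscle development, at -2.54 ± 0.15, and the crest regulator PAX7, which was at least 2.29-fold higher in the frontonasal mass. The forebrain list was also called lower in the mandibular pools, with 7 of 19 measured members lower, 0 higher and 12 not passing, or 9 lower adjusted over the list alone (adjusted p = 1.19e-05, and adjusted p = 0.115 with an estimated correlation). The members were led by ZIC1, SIX3, ZIC2 at -2.14 ± 0.13 and DMRT3, a telencephalic gene, at least 4.86-fold higher in the frontonasal mass.

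Signalling genes differed in smaller sets. PTCH1 and HHIP, receptors and targets of hedgehog signalling, were higher in the mandibular pools by 1.49 ± 0.13 and 1.97 ± 0.21, and ID1, a BMP target, by 1.51 ± 0.17 (adjusted p = 0.00082, 0.00197 and 0.00267). CYP26A1, which degrades retinoic acid, fell by 2.06 on the log2 scale (SE 0.29, adjusted p = 0.008). ALDH1A3, which makes retinoic acid, was lower by -1.35 ± 0.22 (adjusted p = 0.0157), a call lost in 4 fits that left out 1 array, with the highest adjusted p of 0.0662 without mandibular pool 3. The FGF list of 33 genes was called lower with 4 members lower, 0 higher and 29 not passing (7 lower and 1 higher adjusted over the list alone, adjusted p = 0.028, and adjusted p = 0.189 with an estimated correlation). Its call was lost without frontonasal pool 1 (0.0907), frontonasal pool 2 (0.0563) or mandibular pool 3 (0.0712). FGF8, a signal of the nasal pits and oral ectoderm, differed by -1.09 ± 0.18 and its feedback inhibitor SPRY2 by -0.70 ± 0.09 (adjusted p = 0.0164 and 0.00469), and FGF8 lost its call in 3 such fits, with the highest adjusted p of 0.0727 without mandibular pool 2. The notch list of 18 genes was called lower (adjusted p = 0.0211, and adjusted p = 0.273 with an estimated correlation) through the ligand DLL1 at -1.54 ± 0.13 and the target HES5 at -1.36 ± 0.14, with 16 members not passing and 5 lower and 2 higher adjusted over the list alone. That call was lost without frontonasal pool 1 (0.0901) or mandibular pool 1 (0.0555). The retinoid list was not called (0.109), except without frontonasal pool 3 (0.0222).

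Markers of other cell types also differed between mandibular and frontonasal pools. The endothelial list was called higher in the mandibular prominence, with 7 of 25 members higher, 0 lower and 18 not passing, or 12 adjusted over the list alone (adjusted p = 3.42e-06, and adjusted p = 0.236 with an estimated correlation). CD34 rose by 1.47 ± 0.15 and SOX18, a regulator of vessel growth, by 1.29 ± 0.13. The median deviation of these genes from their mean over all arrays was -0.40, -0.01 and -0.34 in frontonasal pools 1, 2 and 3, so pool 2 stood apart within its group. The pharyngeal endoderm list was called higher through PAX9 (1.24 ± 0.14) and FOXI2 (0.86 ± 0.12), with 15 of 17 not passing and 5 higher adjusted over the list alone (adjusted p = 0.00196, and adjusted p = 0.396 with an estimated correlation). Here too frontonasal pool 2 stood apart, with a median deviation of 0.07 against -0.61 and -0.38 in the other pools of its group. The erythroid list of 18 genes was called lower, with 17 not passing and 2 lower adjusted over the list alone (adjusted p = 0.00353, and adjusted p = 0.396 with an estimated correlation). Its 1 called member, the red cell anion exchanger SLC4A1 at -0.87 ± 0.17, had the highest adjusted p of 0.14 without mandibular pool 1. The list of sensory and cranial neurons was called lower with 2 of 25 members lower, 23 not passing and 4 lower and 3 higher adjusted over the list alone (adjusted p = 0.0376, and adjusted p = 0.209 with an estimated correlation). The called members were the neuronal determinants NEUROG1 and NEUROG2, whose frontonasal signals of 29.5 ± 9.12 and 29.6 ± 5.61 lay above background on 1 and 0 of the 3 arrays. The call of the neuron list was lost without frontonasal pool 1 (0.203), without mandibular pool 3 (0.0695) and without the dimmest 40% of probe sets (0.993). The lists of skeletal progenitors, neural crest mesenchyme, surface and oral epithelium, and the maxillary and proximal arch were not called between mandibular and frontonasal pools (0.341, 0.433, 0.521 and 0.327). Fry, however, called the maxillary and proximal arch list higher (fry adjusted p = 0.00081), with DLX1 and LHX8 higher and TBX22 and CYP26A1 lower.

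The second comparison set the maxillary prominence, which joins the frontonasal mass to form the upper jaw, against the frontonasal mass. LHX8 had a maxillary signal of 1816 ± 214 (SD, n = 3) against 18.6 ± 9.68, at least 53.5-fold higher, with a log2 difference of 5.76 ± 0.19 (limma adjusted p = 8.67e-06). COL9A1, a cartilage collagen gene, was at least 11-fold higher in the maxillary pools, MAB21L1 at least 9.94-fold and DLX1 at least 6.73-fold. SP8 differed by -3.41 ± 0.20, and ZIC1 and LMO1, a LIM-only transcriptional cofactor, were at least 8.54-fold and 7.18-fold higher in the frontonasal mass. DLX6 fell by 1.65 on the log2 scale (SE 0.23, adjusted p = 0.00799), whereas ALX1 at -0.67 ± 0.14 and PAX6 at -0.72 ± 0.18 did not pass (adjusted p = 0.0566 and 0.104).

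A total of 866 probe sets differed between maxillary and frontonasal pools, 350 higher and 516 lower in the maxillary prominence, 310 of them by at least 1 on the log2 scale. The 8 largest positive differences, chosen in the same way, were those of LHX8, MAB21L1, COL9A1, DLX1, HDAC9, WNT2B, MAB21L2 and PTN, from 5.76 down to 2.30. The largest negative ones were those of SP8, ZIC1, SOX3, HRASLS, NR2E1, NHLH2, LMO1 and SST1, from -3.41 to -2.56. NR2E1, a nuclear receptor of forebrain progenitors, had a frontonasal signal of 96.2 ± 23.3 against 2 ± 0.411 in the maxillary pools and was at least 2.67-fold higher. PTN, a secreted growth factor, lost its call in 2 fits, with the highest adjusted p of 0.0611 without maxillary pool 2. A fit to only the 6 maxillary and frontonasal arrays called 412 probe sets. The count of probe sets was 535, 424 or 523 without maxillary pools 1, 2 or 3. Without frontonasal pool 2 it was 797, of which 363 were higher and 434 lower. The GAPDH ratio was 1.29, 1.25 and 1.19 in maxillary pools, against the frontonasal values given above.

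The list of frontonasal transcription factors was called lower in the maxillary pools, with 6 of 18 members lower, 0 higher and 12 not passing, or 11 lower adjusted over the list alone (adjusted p = 1.65e-06, and adjusted p = 0.189 with an estimated correlation). TFAP2B, a crest and ectoderm regulator, differed by -2.04 ± 0.16, EYA2 by -1.29 ± 0.15 and SIX3 by -1.73 ± 0.22. The forebrain list was called lower with 7 of 19 members lower, 0 higher and 12 not passing, or 10 lower adjusted over the list alone (adjusted p = 3.42e-06, and adjusted p = 0.0948 with an estimated correlation). The notch target HES5 was lower by -1.87 ± 0.14, ZIC2 by -1.44 ± 0.13 and SOX3 by -2.83 ± 0.31. The neuron list was called lower with 4 of 25 members lower and 21 not passing, or 7 adjusted over the list alone (adjusted p = 0.00172, and adjusted p = 0.0948 with an estimated correlation). Besides NEUROG1 and NEUROG2, these were STMN2 at -0.99 ± 0.20 and ELAVL4 at -0.85 ± 0.17, genes of differentiating neurons. Both lost their calls when 1 array was left out, in 7 and 6 of 9 fits, with the highest adjusted p values of 0.16 without maxillary pool 2 and 0.124 without maxillary pool 3. The neuron list was not called without the dimmest 40% of probe sets (0.169).

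The lists of skeletal progenitors and of neural crest mesenchyme were called higher in the maxillary pools, each through a minority of its members. The skeletal progenitor list had 4 of 25 members higher, 0 lower and 21 not passing, or 6 higher and 1 lower adjusted over the list alone (adjusted p = 0.00172, and adjusted p = 0.13 with an estimated correlation). After COL9A1 came TWIST2, a helix-loop-helix gene of skeletal and dermal mesenchyme, at 1.90 ± 0.21, COL9A3 at 1.57 ± 0.13 and LECT1, which encodes chondromodulin, at 0.81 ± 0.17 (adjusted p = 0.0487, highest 0.139 without maxillary pool 2). The other 2 probe sets of COL9A1 were not called in this comparison. Of 24 neural crest mesenchyme genes, 5 were higher, 1 was lower and 18 did not pass, or 7 higher and 3 lower adjusted over the list alone (adjusted p = 0.0125, and adjusted p = 0.452 with an estimated correlation). SNAI1, a regulator of epithelial to mesenchymal transition, rose by 1.57 ± 0.17 and the mesenchymal homeobox gene PRRX2 by 1.21 ± 0.15, while TFAP2B was the lower member. The crest call was lost without frontonasal pool 3 (0.0955) and without the dimmest 40% of probe sets (0.14).

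The list of surface and oral epithelium was called lower in the maxillary pools with 5 of 24 members lower, KRT14 higher and 18 not passing, or 7 lower and 1 higher adjusted over the list alone (adjusted p = 0.0186, and adjusted p = 0.396 with an estimated correlation). DSP, a desmosome gene, differed by -0.85 ± 0.11, the epithelial cadherin CDH1 by -1.09 ± 0.17 and EPCAM by -0.48 ± 0.08. CDH1 and EPCAM lost their calls in 2 and 3 fits, with the highest adjusted p values of 0.0648 and 0.0731 without maxillary pool 2. The list lost its call without frontonasal pool 2 (0.0944) or maxillary pool 1 (0.0558), and its median deviation was -0.06, 0.15 and 0.13 in frontonasal pools 1, 2 and 3. The endothelial list was called higher with 3 of 25 members higher and 22 not passing, or 7 adjusted over the list alone (adjusted p = 0.000711, and adjusted p = 0.396 with an estimated correlation). They were CD34 at 0.99 ± 0.15, SOX18 at 0.74 ± 0.13 and FLI1 at 0.63 ± 0.13, with the highest adjusted p values of 0.052 and 0.109 without maxillary pool 2 and 0.119 without maxillary pool 1. Endothelial genes were again raised in frontonasal pool 2, as given for the mandibular comparison. The erythroid list was called lower (adjusted p = 0.0115, and adjusted p = 0.438 with an estimated correlation) although its 1 called member, the carbonic anhydrase gene CA2, was higher by 1.44 ± 0.21, with 17 not passing and 1 higher and 1 lower adjusted over the list alone. CA2 lost its call in 2 fits, with the highest adjusted p of 0.0537 without maxillary pool 2.

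Among signalling genes, the FGF list had 3 of 33 members lower, 1 higher and 29 not passing, or 9 lower and 2 higher adjusted over the list alone (adjusted p = 0.00172, and adjusted p = 0.0948 with an estimated correlation). FGF13 differed by -1.05 ± 0.12 and SPRY2 by -0.74 ± 0.09. The notch list was called lower through 3 of 18 members, namely DLL1 (-1.49 ± 0.13), HES5 and LFNG (-0.85 ± 0.09), with 15 not passing and 5 lower and 1 higher adjusted over the list alone (adjusted p = 0.028, and adjusted p = 0.296 with an estimated correlation), and its call was lost without frontonasal pool 1 (0.159). ID1 rose by 1.64 ± 0.17 and ALDH1A3 fell by 1.62 on the log2 scale (SE 0.22). PTCH1 rose by 0.88 ± 0.13, and the retinoic acid receptor gene RARB by 0.69 ± 0.12 (adjusted p = 0.0254), a call lost in 5 fits, with the highest adjusted p of 0.0843 without maxillary pool 1 and 0.0532 without frontonasal pool 2. The retinoid, ventral arch, maxillary and endoderm lists were not called between maxillary and frontonasal pools (0.841, 0.803, 0.221 and 0.602), except endoderm without frontonasal pool 2 (0.0304). Fry called the maxillary list higher here (fry adjusted p = 0.00081), with DLX1, LHX8 and MEIS2 higher and TBX22 lower.

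**Figure D1:**
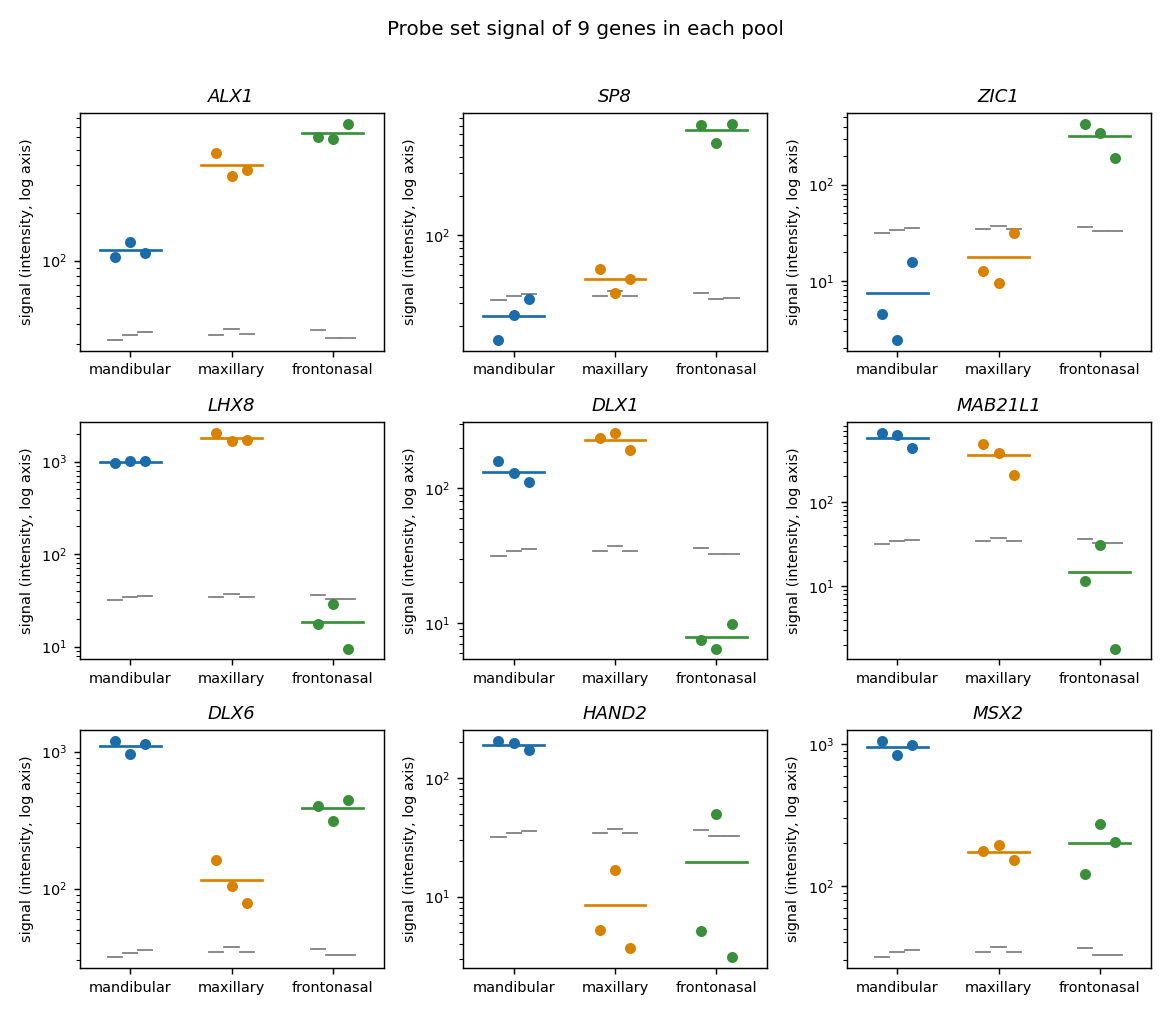
Probe set signal (intensity units, log axis) of 9 genes in the 3 pools of each prominence, with 1 point per pool, a coloured line at the arithmetic mean of the 3 signals and a grey tick at the background of each array. ALX1, SP8 and ZIC1 are brightest in the frontonasal mass, LHX8, DLX1 and MAB21L1 lie below background in the 3 frontonasal pools, and DLX6, HAND2 and MSX2 are brightest in the mandibular prominence.

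The third comparison asked what separates the upper and lower parts of the first pharyngeal arch. DLX6, a distal-less gene that specifies ventral arch identity, had a mandibular signal of 1096 ± 126 (SD, n = 3) against 115 ± 42.5 in the maxillary pools, a log2 difference of 3.13 ± 0.23 (limma adjusted p = 0.00192). HAND2 was at least 5.39-fold higher in the mandibular prominence (3.11 ± 0.43, adjusted p = 0.0336), MSX2 was higher by 2.35 ± 0.24 (0.0115) and BHLHE22, a neuronal helix-loop-helix gene, by 2.58 ± 0.11 (0.000228). ALX1 was lower in the mandibular pools by -1.64 ± 0.14 (0.00643), and LRRC17, which encodes a secreted leucine-rich repeat protein, by -2.38 ± 0.23 (0.00886). LHX8 and DLX1, with log2 differences of -0.84 ± 0.19 and -0.72 ± 0.15, did not pass (0.193 and 0.15).

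Between mandibular and maxillary pools 101 probe sets differed, 66 higher and 35 lower in the mandibular prominence, 58 of them by at least 1 on the log2 scale. A fit to only the 6 mandibular and maxillary arrays called 145. With the replicate number as a block the count was 47, although the labels do not say that equal numbers share embryos or a day. CSRP3, a muscle LIM protein gene, was at least 2.37-fold higher in the mandibular pools. NPY, a neuropeptide gene, rose by 1.78 ± 0.14, CHODL, a membrane lectin gene, by 2.33 ± 0.22 and AKR1D1, a steroid reductase gene, by 2.19 ± 0.24. SOX10 and FOXD3, genes of migrating crest cells and glia, were lower, SOX10 by -1.62 ± 0.20 and FOXD3 at least 1.3-fold, and the maxillary signal of FOXD3, 44.8 ± 11.1, lay above background on 2 of 3 arrays. ADAMTSL1, EYA2, COL9A3 and WSCD2 completed the 8 largest negative differences, at -1.34, -1.25, -1.21 and -1.17. DLX5 rose by 1.15 ± 0.15 and STMN2 by 1.63 ± 0.20, and RARB fell by 0.86 on the log2 scale (SE 0.12). With the replicate block, DLX5 (limma adjusted p = 0.0685), RARB (0.0501), AKR1D1 (0.073) and FOXD3 (0.105) were not called.

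Single arrays weighed heavily on this comparison. The count was 15, 29 or 25 without mandibular pools 1, 2 or 3, 29, 18 or 21 without maxillary pools 1, 2 or 3, and 174 (123 higher, 51 lower) without frontonasal pool 2, which enters through the shared estimate of the spread. Of 25 named genes called here, 6 kept their call with every array left out in turn: ALX1, DLX6, BHLHE22, CSRP3, NPY and LRRC17. The others lost it in 2 to 9 of the 9 fits. Among them the highest adjusted p values were 0.149 for HAND2, 0.082 for MSX2, 0.134 for DLX5, 0.0636 for CHODL, 0.0859 for AKR1D1, 0.134 for FOXD3, 0.103 for EYA2 and 0.0859 for COL9A3, all without mandibular pool 1. Those of SOX10 and RARB were 0.107 and 0.157 without mandibular pool 2, those of ADAMTSL1 and STMN2 0.111 and 0.107 without maxillary pool 1, and that of WSCD2 0.0821 without maxillary pool 2. MSX1 at 0.79 ± 0.12 had an adjusted p of 0.0415 and was not called in any fit without 1 array. Without frontonasal pool 2, HAND2, MSX2 and DLX5 had limma adjusted p values of 0.0011, 0.00341 and 0.0181.

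The ventral arch list was called higher in the mandibular prominence through 5 of 21 members (DLX5, DLX6, HAND2, MSX1 and MSX2), with 0 lower and 16 not passing, or 7 higher and 1 lower adjusted over the list alone (adjusted p = 1.00e-05, and adjusted p = 0.0948 with an estimated correlation). The skeletal progenitor list was called lower through COL9A3, with 24 of 25 not passing and 4 lower and 1 higher adjusted over the list alone (adjusted p = 0.000142, and adjusted p = 0.0948 with an estimated correlation). The neural crest mesenchyme list was called lower, with PRRX2, SOX10 and FOXD3 lower, MSX1 and MSX2 higher and 19 of 24 not passing, or 4 lower and 3 higher adjusted over the list alone (adjusted p = 0.00811, and adjusted p = 0.452 with an estimated correlation), and the call was lost without mandibular pool 3 (0.16) and without the dimmest 40% of probe sets (0.218). The frontonasal transcription factor list was called lower through ALX1 and EYA2, with DLX5 higher and 15 of 18 not passing, or 6 lower and 2 higher adjusted over the list alone (adjusted p = 0.0285, and adjusted p = 0.497 with an estimated correlation). This call was lost without mandibular pools 2 (0.0605) or 3 (0.0695), maxillary pool 2 (0.117) or frontonasal pool 1 (0.0518), and with the replicate block (0.0576).

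Several lists were called between mandibular and maxillary pools with few or no single members passing. The pharyngeal endoderm list was called higher with 0 of 17 members called and 6 higher adjusted over the list alone (adjusted p = 0.00172, and adjusted p = 0.396 with an estimated correlation). The list of surface and oral epithelium was called higher with 0 of 24 members called, also adjusted over the list alone (adjusted p = 0.00178, and adjusted p = 0.273 with an estimated correlation). The endothelial list was higher with 0 of 25 called and 2 higher adjusted over the list alone (adjusted p = 0.00602, and adjusted p = 0.452 with an estimated correlation), and its call was lost without mandibular pool 2 (0.0688). The maxillary and proximal arch list was lower in the mandibular pools with 0 of 15 called and 4 lower and 1 higher adjusted over the list alone (adjusted p = 0.0303, and adjusted p = 0.209 with an estimated correlation). It was not called without mandibular pools 1 (0.065) or 3 (0.101), without maxillary pool 2 (0.0514), or with a pseudocount of 1 (0.0536). The retinoid list was lower through RARB, with 20 of 21 not passing and 3 lower and 1 higher adjusted over the list alone (adjusted p = 0.036, and adjusted p = 0.452 with an estimated correlation). Its call was lost without mandibular pools 1 (0.0718) or 3 (0.105), maxillary pools 1 (0.0669) or 3 (0.0749) or frontonasal pool 1 (0.0608). The call was also lost with quantile normalization (0.0546), unscaled values (0.0537) or the replicate block (0.0552). The FGF, notch, neuron, forebrain and erythroid lists were not called between mandibular and maxillary pools (0.407, 0.674, 0.327, 0.479 and 0.394).

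Probe sets that set 1 prominence apart from both others were counted from the same fit. The frontonasal mass had 333 probe sets higher and 193 lower than in both other prominences, among them SP8, ZIC1, SOX3, PAX7 and TFAP2B on the higher side and LHX8, DLX1, MAB21L1, WNT2B, HDAC9 and ID1 on the lower side. The mandibular prominence had 49 higher, including HAND2, DLX6, MSX2 and BHLHE22, and 21 lower, including ALX1. The maxillary prominence had 13 higher, including RARB and COL9A3, and 16 lower, including DLX6. Independent lists of these sizes would share 6.98 and 4.13 probe sets for the frontonasal mass, 0.78 and 0.473 for the mandibular prominence, and 0.319 and 0.886 for the maxillary prominence, and 20 simulations with no effect gave a mean of 0 for each. Without any effect almost no probe set is called, and independent lists leave out the shared arrays, so neither value measures how far the observed counts exceed chance. With 1 array left out, the mandibular prominence had from 9 (without mandibular pool 1) to 95 (without frontonasal pool 2) probe sets higher and from 3 to 28 lower, and the maxillary prominence from 1 to 17 higher and from 3 to 21 lower, with the same arrays at the ends. The frontonasal mass had from 194 to 305 higher and from 103 to 270 lower, fewest without maxillary pool 2 and most without frontonasal pool 2.

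Both comparisons with the frontonasal mass use the same 3 arrays, which alone makes their results alike. Across probe sets, which are not independent replicates, their log2 differences correlated at r = 0.728, against 0.499 in simulations with no effect. The covariance was 0.0634 against a simulated 0.0146, a difference of 0.0487. Of 529 probe sets called in both comparisons, 526 went in the same direction. The simulations share the frontonasal arrays in the same way but hold no effects. They also give each probe set the same spread in every prominence, while the real frontonasal pools varied more. The simulated correlation and covariance may therefore be too low, and the difference of 0.0487 too large. The 3 frontonasal arrays are too few to leave each comparison 2 of its own, so part of the agreement in correlation and in calls may come from the shared arrays.

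In the preset panel of craniofacial genes, 31 of 36 were measured. ALX4, DLX3, HAND1 and LHX6 were not above background on any array, so no fold is given for them. BARX1, a homeobox gene of jaw mesenchyme, had signals of 1627 ± 206, 988 ± 152 and 650 ± 489 (SD, n = 3) in mandibular, maxillary and frontonasal pools. Its difference between mandibular and frontonasal pools was 1.53 ± 0.40 (adjusted p = 0.114), and 2.09 (0.000554) without frontonasal pool 2. Between maxillary and frontonasal pools its adjusted p was 0.428, and 0.00454 without frontonasal pool 2 (log2 difference 1.38). Without that pool, BMP7 was also called between mandibular and frontonasal pools (-0.96, 0.00684), and EDNRA between maxillary and frontonasal pools (-0.67, 0.0435). In the main fit they had 0.0675 and 0.108. SHH, the hedgehog ligand gene, had signals of 54.3 ± 4.05, 31.6 ± 3.02 and 28.5 ± 10, with a mandibular to frontonasal difference of 0.68 ± 0.15 (0.0547, and 0.00462 without frontonasal pool 2). FGF8 between maxillary and frontonasal pools differed by -0.74 ± 0.18 (0.0905, and 0.0104 without frontonasal pool 2). EDN1, BMP4, NOG, WNT11 and ALDH1A2 were not called in any comparison, and the frontonasal signal of ALDH1A2, a retinoic acid synthesis gene, was 277 ± 267. DLX5 between maxillary and frontonasal pools was not called (-0.40 ± 0.15, adjusted p = 0.267), while its 1 other probe set was called in the opposite direction (3.03), and between mandibular and maxillary pools that probe set also had the opposite sign (-0.89, adjusted p = 0.0935).

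Frontonasal pool 2 carried transcripts known from other organs. In that pool 47 genes were more than 2 log2 units above the mean of the other frontonasal pools, against 0 to 2 genes on each other array compared with the rest of its own group. FGB, which encodes a fibrinogen chain made by liver, had a signal of 2292 there and 49.5 and 50.6 in pools 1 and 3. TTR, a liver and yolk sac transport protein gene, had 1699 against 101 and 236, and the cardiac and gut regulator GATA5 1069 against 6.36 and 85.1. GATA5 was also present in the mandibular pools, at 290, 316 and 298 against 4.77, 2.61 and 25 in the maxillary pools. HOXA3, a gene of the posterior arches, had 216 against 9.77 and 11.8. LHX8 with 28.8 against 17.5 and 9.52 and DLX1 with 6.46 against 7.47 and 9.83 stayed below background in all frontonasal pools, but other genes with high mandibular signals were raised in pool 2. HAND2 was called higher in the mandibular prominence than in both others. ISL1 and BARX1 were not called in any comparison of the fit to all arrays. Signals of HAND2, ISL1 and BARX1 were 50.0, 363 and 1214 in this pool, against at most 5.15, 47.6 and 373 in the other frontonasal pools. NKX2-5, a cardiac regulator, had 90.7 against 2.42 and 1.05.

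**Figure D2:**
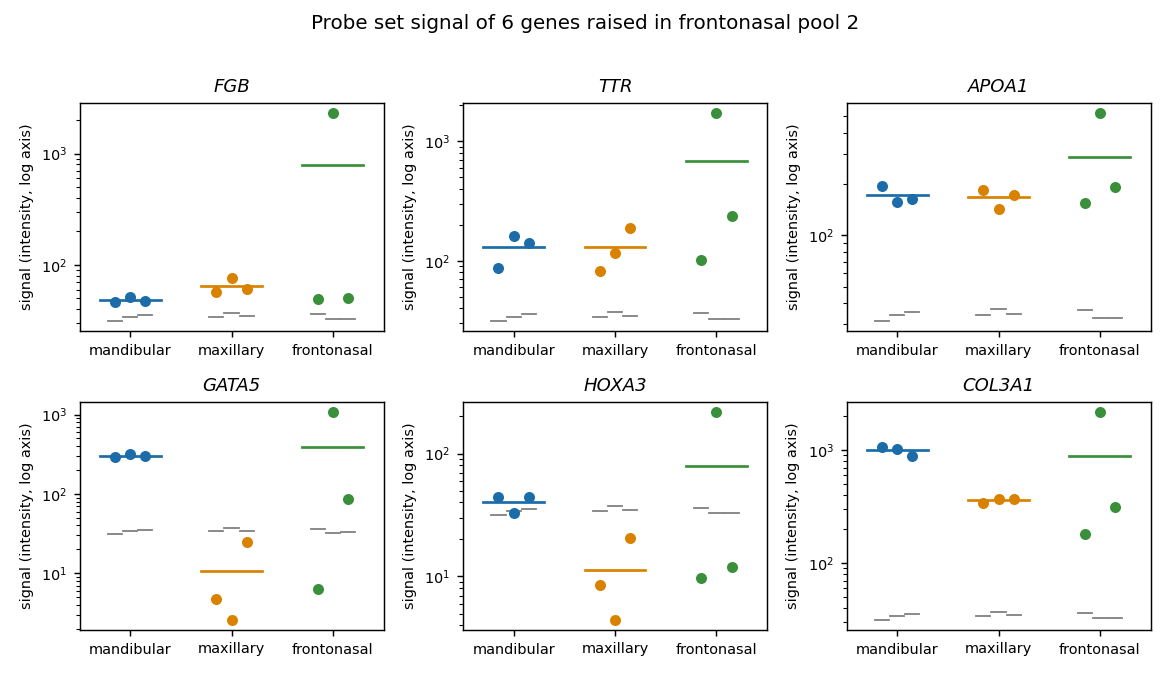
Probe set signal (intensity units, log axis) of 6 genes in the 3 pools of each prominence, with 1 point per pool, a coloured line at the arithmetic mean of the 3 signals and a grey tick at the background of each array. The middle frontonasal point is pool 2, with 2292 for FGB, 1699 for TTR, 519 for APOA1, 1069 for GATA5, 216 for HOXA3 and 2172 for COL3A1, above every other pool, and the genes were chosen after their values were seen.

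The remaining lists were not called by camera in any comparison. Their camera adjusted p values are given in the order mandibular against frontonasal, maxillary against frontonasal, mandibular against maxillary. BMP pathway genes had 0.0689, 0.175 and 0.352, with FST, ID1, MSX1 and MSX2 higher in the mandibular than in the frontonasal pools, and the list was called without frontonasal pool 2 in the first 2 comparisons (0.011 and 0.0164), and in the first without mandibular pool 2 (0.0475) or without the dimmest 40% of probe sets (0.0151). Hedgehog pathway genes had 0.0721, 0.394 and 0.0549, and were called in the first and the last comparison without frontonasal pool 2 (0.038 and 0.0155) or mandibular pool 3 (0.0468 and 0.0326), in the first without frontonasal pool 1 (0.00946), and in the last without maxillary pools 1 (0.00903) or 2 (0.0482). Without the dimmest 40% of probe sets it was called in the same comparisons (0.0247 and 0.0144). WNT pathway genes had 0.327, 0.341 and 0.841, although WNT2B was at least 3.21-fold higher in the mandibular and at least 3.58-fold higher in the maxillary than in the frontonasal pools, and the WNT antagonists SFRP1 and SFRP2 were lower in the mandibular than in the frontonasal pools by -1.10 ± 0.10 and -1.07 ± 0.09. Nasal placode, lens and eye genes had 0.498, 0.479 and 0.135, the last of which was 0.0144 without the dimmest 40% of probe sets. Between mandibular and frontonasal pools, fry called the placode list lower (fry adjusted p = 0.0452) and the BMP list higher (0.0492). Guidance cues had 0.804, 0.599 and 0.952, with the ephrin receptor gene EPHA3 higher in the mandibular than in the frontonasal pools by 2.55 ± 0.18. Branchiomeric muscle genes had 0.622, 0.859 and 0.401, with MYL4, an embryonic and atrial myosin light chain gene, at 610 ± 108 in the frontonasal mass against 127 ± 14.3 and 161 ± 34.7 in the mandibular and maxillary pools, and MYF5, the first muscle determinant, below background in the frontonasal mass.

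HOX genes, with 0 of 24 measured members called in any comparison, had adjusted p values of 0.446, 0.602 and 0.753. Macrophage and leukocyte genes had 0.896, 0.883 and 0.646, cell cycle genes 0.841, 0.674 and 0.393, hypoxia and glycolysis genes 0.885, 0.952 and 0.987, and immediate early and heat shock genes 0.599, 0.871 and 0.599. In all called lists the median, the mean and the test had the same sign. In 15 of the 47 other list tests they did not, for example nasal placode genes between mandibular and frontonasal pools, with a median of 0.09, a mean of -0.24 and a lower direction in the test, and WNT genes between mandibular and maxillary pools, with a median of 0.01, a mean of 0.04 and a lower direction in the test. Of the W chromosome genes only 4 were measured, too few for a list test, and none was called between prominences (smallest adjusted p = 0.633, for HINTW).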

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

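The split into higher and lower calls without frontonasal pool 2 was the alternative setting added after seeing the data. Named genes were refitted with the replicate block, quantile normalization, median centring, without the dimmest 40% of probe sets and without each array. In these fits no called difference turned its direction, but 59 of 166 lost the call in at least 1. Where 1 array was left out, the remaining pair of its group was assumed to vary like the other groups, and the causes of the other changes were not tested. Counts of probe sets are in the order mandibular against frontonasal, maxillary against frontonasal, mandibular against maxillary. They were 1034, 935 and 111 with quantile normalization, 1021, 937 and 119 with limma-trend, and 1022, 926 and 100 with unscaled values, and median centring coincided with the scaling used. A minimum log2 difference of 1 left 350, 310 and 58 probe sets, and a test against a fold of 1.5 left 139, 113 and 10, both stricter by construction. A pseudocount of 1 gave 602, 531 and 35, with 622 in the F test, 17 higher and 7 lower in the mandibular prominence than in both others, 4 and 9 in the maxillary prominence, 192 and 120 in the frontonasal mass, and frontonasal distances of 0.330 (mandibular) and 0.315 (maxillary). Without the dimmest 40% of probe sets these distances were 0.278 and 0.263, and the maxillary prominence had 24 higher and 26 lower. Fits to only the 6 arrays compared, which have fewer degrees of freedom, gave 613, 412 and 145, and array weights gave 888, 800 and 159. Frontonasal pools varied more. Genes more than 1 log2 unit below the rest of their group numbered 116, 55 and 93 on the frontonasal arrays and 19 to 34 on the others. The main fit uses 1 spread for all prominences, so its counts, and the contrast between them, depend in part on that shared estimate.

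The labels do not say that equal replicate numbers share embryos or a day. Residuals of equally numbered arrays correlated at 0.0166 to 0.120 over all tested probe sets, not above 0.1 throughout. Over probe sets above the median mean they reached 0.0786 to 0.234 between mandibular and frontonasal, 0.0558 to 0.0921 between maxillary and frontonasal and 0.158 to 0.170 between mandibular and maxillary arrays. Each was the highest for its array in 9 of 9 comparisons, a hint from the data alone. With the number as a block, the counts were 830, 684 and 47, with 785 in the F test, 25 higher and 11 lower in the mandibular prominence, 4 and 7 in the maxillary prominence, 282 and 146 in the frontonasal mass, and 26 lists called. The lists not called with it were, between mandibular and maxillary pools, frontonasal transcription factors (0.0576) and the retinoid pathway (0.0552). Of the calls of named genes, 17 ended with the block. Between mandibular and maxillary pools these were DLX5 (0.0685), RARB (0.0501), AKR1D1 (0.073), FOXD3 (0.105), NOTUM (0.0555), FST (0.0878), FGF13 (0.0848) and EPHA3 (0.0842). Between mandibular and frontonasal pools they were DLX5 (0.0526), EFNB1 (0.0659), DSP (0.0637) and HSPB9 (0.054), and between maxillary and frontonasal pools NBL1 (0.0702), ETV1 (0.0591), LAMA5 (0.0511), STMN2 (0.0544) and SOX18 (0.0539). In limma, 0 probe sets differed by replicate number at an adjusted p under 0.05, and 3208 did at an unadjusted p under 0.05. The latter is more than the share of 0.05 of the 38439 tested probe sets that no effect would give on average. The 0 adjusted calls therefore do not show that the number has no effect.

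Leaving out each array in turn gave 526 to 1089, 424 to 797 and 15 to 174 probe sets, and 627 to 1009 in the F test. The mandibular prominence had 9 to 95 higher and 3 to 28 lower, the maxillary prominence 1 to 17 and 3 to 21, the frontonasal mass 194 to 305 and 103 to 270. The distances were 0.225 to 0.259, 0.209 to 0.236 and 0.0814 to 0.122. Lists called ranged from 23 to 31, and 26 of the 31 called without frontonasal pool 2 were among the 28. With an estimated correlation camera called 0 lists (28 with the preset one), and fry called 22, not all of them among the 28. Probe sets near background limit what dim genes can show.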

Other observations

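The tests of an array-wide artefact, of pools numbered 2, of forebrain and of surface epithelium were chosen after the result was seen. Those of chance and of neighbouring genes were written down before it. The liver test was prompted by genes already seen raised in frontonasal pool 2. It was written down before the liver genes it uses had been looked at.

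Adjacent genes were called together in several places. MAB21L1 and its neighbour NBEA were both higher in the maxillary than in the frontonasal pools, at least 9.94-fold and by a log2 difference of 0.79, and DLX1 and METAP1D were both higher there, at least 6.73-fold and by 1.33. PAX9, a gene of pharyngeal endoderm and jaw mesenchyme, and SLC25A21 were higher in the maxillary than in the frontonasal pools by 1.55 and 0.73. COL6A1 and COL6A2, genes of a matrix collagen, were lower in the mandibular than in the frontonasal pools by -2.17 and -1.35. A probe set of GLIPR1L varied between pools of every prominence. Its signals were 148, 3.08 and 261 in mandibular, 218, 18.6 and 5.58 in maxillary and 219, 7.09 and 4.62 in frontonasal pools 1, 2 and 3. In limma's test for an effect of the replicate number, it had an adjusted p of 0.568.

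Splits of the arrays into other groups of the same sizes gave fewer calls. Of 100 splits of the 9 arrays, only the real one (1) reached 1014 probe sets in the F test (highest other 413), 526 probe sets set apart in 1 prominence (364) and 28 lists called (17). A chance division of the arrays is therefore unlikely to give these totals, but it is not excluded. The totals do not speak for any single list call, since other splits called lists as well. For the pairwise counts the 10 splits of 6 arrays are too few for a share under 0.05, with real values of 974, 866 and 101, each reached by 1 split, and highest others of 1, 0 and 2.

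Frontonasal pool 2 held transcripts of visceral organs. Against raised background on that array stands the median log2 difference of -0.0231 of the virus and reporter probe sets to pools 1 and 3, and against a batch shared by the pools numbered 2 stands the larger median of 0.0235 for the liver genes seen first in mandibular and maxillary pool 2. Liver tissue carried into the pool may be a source. The 25 liver genes not looked at before had a median of 0.54, at percentile 100 of random lists matched on signal. Of them 4 were above background on all other arrays, and 8 were raised by more than 1 log2 unit. The latter included F2 (157 against 1.68 and 1.11 in pools 1 and 3), FETUB (88.7 against 6.15 and 4.35) and KNG1 (81.1 against 7.37 and 3.68). But ALB (55.8 against 40.4 and 37.7) and APOB (30.9 against 33.0 and 17.8), abundant in mature liver, were hardly raised. Lists for heart (0.29, percentile 99.8) and for pancreas and gut (0.35, percentile 99.9) were raised too. Among heart genes raised by more than 1 log2 unit, TNNC1 and MYH15 exceeded all mandibular signals. NKX2-5 (90.7) and TNNT2 (115) lay within them (55.2 to 93.4 and 87.8 to 129). Among such gut genes, GCG, FOXA2 and PROX1 exceeded all mandibular signals, and SOX17 (224) did not (231 to 324). Some members of these lists are therefore not particular to visceral organs. However, LHX8 and DLX1 stayed below background in pool 2 (28.8 and 6.46), against 956 to 1025 and 111 to 160 in the mandibular pools. Tissue like the mandibular pools, in an amount that gave those levels, would have raised them. Lists for nephric tissue (-0.07, percentile 25.5) and for limb and somites (-0.12, percentile 6.98) were not raised. The frontonasal genes taken as a negative control were lower in pool 2 (-0.43, percentile 0). All of them but ZIC1 (0.27) were below the mean of pools 1 and 3, for example SP8 with 511 against 703 and 721. The source stays open. No biological explanation was tested, as the design names none for a single pool.

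From the forebrain, placode and frontonasal transcription factor lists, 13 genes called higher in the frontonasal mass than in both other prominences were taken as regulators. Their median log2 difference was -1.91, which follows from this choice. PAX3, PAX7, TFAP2B and SP8 belong to the frontonasal list alone. The placode list as a whole was not called against the frontonasal mass (camera adjusted p = 0.498 mandibular and 0.479 maxillary). Whether a larger share of surface epithelium was their cause could not be decided. The 24 epithelial genes as a whole shifted little, with a median of -0.19 and a 25th percentile of -0.43. But the regulators were picked for being called, so their median cannot be set against that of an unselected list. CDH1 (-0.97) went beyond the least extreme regulator (-0.70). EPCAM (-0.37) was also lower than in the frontonasal mass, and KRT14 (0.82) was higher. Forebrain tissue in the frontonasal pools may contribute and cannot be told apart from expression in the prominence itself, because of the 8 forebrain genes outside the placode and frontonasal lists and not among the regulators (median -0.0754 between mandibular and frontonasal pools) only 3 were above background on all frontonasal arrays. Of these NES was lower in both other prominences (-0.59 and -1.18), FABP7 (0.19 and 0.28) and LIN28A (0.03 and -0.13) were not. A difference between the prominences themselves stays open as well.

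Neighbouring genes might share regulation. Among 10332 adjacent pairs, 26 were called in the same direction, 8 of them in 2 comparisons, which gave 34 calls over the 3 comparisons against a mean of 16.6 in 10000 shuffles of gene positions (95th percentile 25, one-sided permutation p = 0.0008). Without tandem relatives such as DLX5 and DLX6, 19 of 9974 pairs gave 22 calls (mean 16, 95th percentile 24, permutation p = 0.125). No excess beyond tandem gene families was shown, but with so few called pairs a small one is not excluded. Members of tandem families may carry the difference.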
